A study of Homo sapiens with 10 samples.

How the data were processed

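Counts per gene were deposited by the authors for 10 libraries in 1 table and were used without further correction. Per the submitters' processing notes, base calls were converted with bcl2fastq, reads were aligned to hg19 with TopHat2 2.0.6, and gene counts were made with HTSeq, whose version, annotation and strand setting are not stated. Every count was even, with 0 odd values, which would follow from counting each read pair as 2. Whether read pairs were counted in that way is not stated, so the counts were kept as deposited, and read pairs were taken as the counts divided by 2. RPKM values were deposited beside the counts by the authors, and within a library each equalled the count divided by gene length and by a single constant. They were not used further. Gene start, stop and coding length were deposited by the authors in hg19 coordinates, per the file headers and the submitters' processing notes, and served for positions and for the length correction. RNA had been isolated with the Direct-zol RNA Miniprep Kit of Zymo Research and libraries made with an Illumina mRNA kit.

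The table held 23398 genes. For 49 symbols listed more than once a single entry was kept, which removed 52 entries, and 102 genes of the Y chromosome or the X-inactivation centre were removed because the donors are people, leaving 23244. The table held 0 genes of the mitochondrial genome. The 10 libraries formed 8 units: counts of both low biopsies were summed, as were those of high replicates 1 and 2, because the labels assign each pair to 1 construct, and the other high biopsies, HUVEC and HLSEC stood alone. Genes were kept with filterByExpr by group in edgeR 4.0.16 under R 4.3.3, which left 16496, and libraries were scaled by TMM. CPM of single libraries were scaled over the 10 libraries, while the mean and SD of the high constructs and the ratios without replicates were scaled over the 8 units.

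Differential expression was tested with edgeR's quasi-likelihood fit over all groups, with high minus low, high minus HUVEC and high minus HLSEC as contrasts, and p-values were adjusted by the Benjamini-Hochberg method at 0.05. The replicates behind each p-value were the 5 high constructs alone, with 4 residual and 5.38 prior degrees of freedom. The unreplicated low construct, HUVEC and HLSEC were assumed to vary as the high constructs did. The biological coefficient of variation was 0.13 between biopsies of the low construct, 0.181 between biopsies of the high construct and 0.304 between high constructs, against 0.317 in the fit. SE values were derived from the log2 fold change and the F statistic. Distal and proximal biopsies were compared in a fit of 15272 genes with the construct as a block. Gene lists, 39 lists with 719 genes written before the data were examined, were tested with camera in limma 3.58.1 at its preset correlation of 0.01 where at least 5 members were expressed, with adjustment over the lists of a contrast. Counts adjusted over the list alone used the Benjamini-Hochberg method within a list. Every list was also tested with the correlation estimated from the data and with fry.

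Named genes followed a rule fixed in advance. It took, for each contrast, the 6 largest called changes in each direction at a log2 CPM of at least 3. It added up to 4 called members of each list, or otherwise the members with the smallest p, and a panel of endothelial, glucose, proliferation and other cell type markers. For contrasts without replicates and for biopsy position, the largest and smallest ratios at an average log2 CPM of at least 5 were taken with the panel. HLSEC and the low construct were compared with HUVEC as ratios of CPM + 0.5, and the list medians were set against 10000 random lists matched over 20 expression bins. Intervals on ratios were 95% intervals from these read pairs and cover counting error only. Where a group had no count, ratios were bounded with a floor of 3 read pairs.

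Alternatives comprised DESeq2 1.42.0, limma with voom and the construct as a random effect (correlation 0.72), RLE scaling, library totals, no filter, a filter of 5 CPM in at least 3 units and only the compared groups in the fit. They further comprised each biopsy as a sample, a test against a 1.5-fold change, a term for biopsy position, a replicate block, and leaving out each library of the constructs or the high construct with replicates 1 and 2. GC content came from GENCODE 29 by symbol, found for 14389 of the genes (87.2%), and its trend was removed together with that of gene length as an offset per unit. In 3 simulations of the comparison of high with low constructs on 16335 genes, planted changes of 2-fold, 4-fold and 8-fold were called in 4.5%, 40.8% and 75.3% of 199, 201 and 198 genes, with 18 false calls and 0 of 60 random lists called. For the comparison with HLSEC, on 16336 genes, the shares were 2.5%, 44.5% and 74.2% with 25 false calls. Genes were drawn independently in these simulations, so the random lists could not test calls of lists whose members vary together. Against the low construct the estimated correlation was 0.915 for the G2/M list and 0.845 for the ribosomal protein list. TMM factors ranged from 0.919 to 1.115. Dimension 1 of a multidimensional scaling held 32.9% of the variance and set HLSEC (-3.59) apart from all other libraries (-0.325 to 0.67).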

Results

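Messenger RNA was sequenced from reendothelialized bioengineered liver constructs, seeded with human umbilical vein endothelial cells (HUVEC) and kept in a perfusion bioreactor, at a phase of low or of high glucose consumption. The low phase comprised 2 biopsies, 1 proximal and 1 distal, which the labels assign to the same construct. The high phase comprised 6 biopsies: a proximal and a distal one from the same construct, and 4 from mid sections, each assumed to come from its own construct, giving 5 high constructs. Cultured HUVEC and human liver sinusoidal endothelial cells (HLSEC), both grown on plastic, gave 1 library each. Library totals were 82.3 M counts for HUVEC, 78.6 for HLSEC, 62.4 and 67.4 for low replicates 1 and 2, and 78.9, 65.2, 84.3, 64.2, 82.3 and 69.7 for high replicates 1 to 6. Every count was even, and if each read pair was counted as 2, which the labels do not state, the totals correspond to 31.2 to 42.1 M read pairs. The most abundant transcript in each of the 10 libraries, EEF1A1, a translation elongation factor, took 1.5% to 3.16% of the counts. Changes are log2 fold changes ± SE, and expression levels are CPM, counts scaled to the size of the library, with the SD over the 5 high constructs. The low construct, HUVEC and HLSEC had no replicate construct or culture, and the difference in RNA extraction solution between the low biopsies and all other libraries coincided with the phase.

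The first comparison asked which genes differed between constructs at high and at low glucose consumption. Mitotic and DNA replication genes were lower in the high constructs, and ribosomal protein genes, p53 target genes and interferon-stimulated genes were higher, by list tests that were all lost with an estimated correlation (adjusted p = 0.679). MKI67, a marker of proliferating cells, was at 177 and 244 CPM in the low biopsies and at 70.2 ± 35.8 CPM in the 5 high constructs, a log2 fold change of -1.57 ± 0.52. CDKN1A, the cyclin-dependent kinase inhibitor p21, was at 237 and 223 CPM against 461 ± 83.7 CPM, a log2 fold change of 1.03 ± 0.32. No single gene passed the threshold in edgeR's quasi-likelihood test (0 higher and 0 lower of 16496; smallest adjusted p = 0.297). At an unadjusted p under 0.05, 519 genes were higher and 765 lower, where chance alone gives 825. DESeq2 called 25 higher and 43 lower, and limma with voom called 0 in either direction. In 2116 genes all 6 high biopsies lay above both low biopsies and in 2235 all lay below. Both low biopsies came from 1 construct, so these counts carry no test of the phase.

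Among the cell cycle genes, all 26 tested members of the G2/M list were lower in the high constructs, with a median log2 fold change of -1.18 (camera adjusted p = 6.76e-16). That median ranged from -1.65 to -0.97 when 1 library was left out. The mean log2 CPM of the list was 4.23 to 4.56 in high replicates 1, 2, 3 and 6. It was 5.34 in high replicate 4 and 5.94 in high replicate 5, against 6.07 and 6.37 in the low biopsies. In the S phase list 26 of 27 members were lower, with a median of -0.88 (adjusted p = 1.54e-12). Besides MKI67, the spindle assembly factor TPX2 was at -1.49 ± 0.47, and the replicative helicase subunits MCM4 and MCM7 were at -1.36 ± 0.45 and -0.86 ± 0.27. All 22 p53 targets were higher, with a median of 0.62 (adjusted p = 2.42e-07), including CCNG1 at 1.31 ± 0.34. The ribosomal protein list was higher in all 34 members, with a median of 0.94 (adjusted p = 5.64e-21). RPL11 reached 1.14 ± 0.31, RPL7A 1.06 ± 0.31, and 25 members passed when adjusted over the list alone. Interferon-stimulated genes were higher in 25 of 29 members, with a median of 0.60 (adjusted p = 8.5e-06), and genes of the NRF2 antioxidant response in 14 of 15, with a median of 0.39 (adjusted p = 0.00828). Within the latter the ferritin chains FTL and FTH1 stood at 1.49 ± 0.40 and 0.79 ± 0.33, and the median of the list was 0.25 without high replicate 5. For these 6 lists the adjusted p was 0.679 with an estimated correlation, so none of their calls held with it. The 85 ribosomal protein genes together took 10.4% to 15.2% of the counts in the 6 high biopsies and 7.2% and 7.5% in the low ones, 6.2% in HUVEC and 5.3% in HLSEC.

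**Figure D1:**
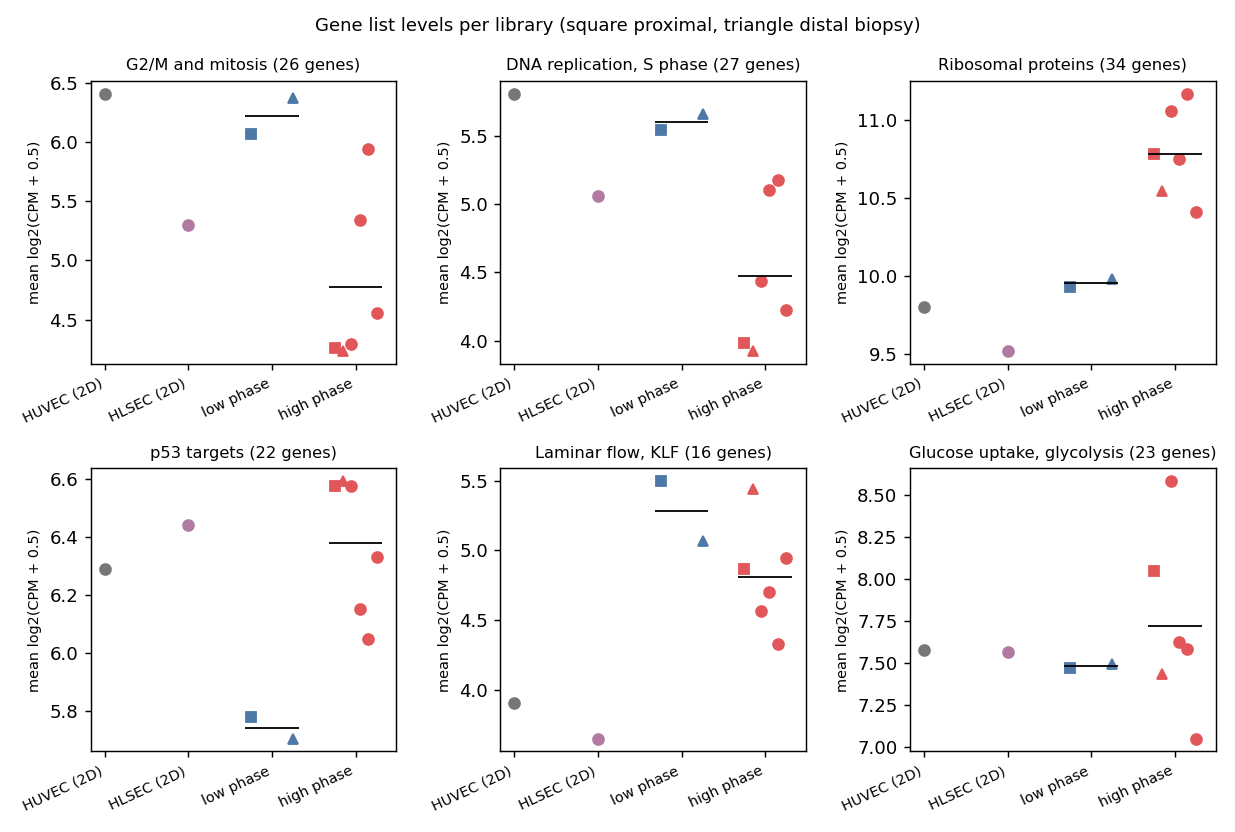
Mean log2(CPM + 0.5) over the tested members of 6 gene lists (vertical axis) in each of the 10 libraries by group (horizontal axis); squares are proximal biopsies, triangles distal biopsies, circles all other libraries, and black lines the mean over the libraries of a group. The 6 high biopsies lie below both low biopsies for the G2/M and S phase lists and above them for the ribosomal protein and p53 lists.

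Genes of glucose uptake and glycolysis did not pass as a list (median 0.26, 17 of 23 higher, adjusted p = 0.254). The glucose transporter SLC2A1 was at 0.57 ± 0.98, hexokinase HK2 at 0.18 ± 0.84 and lactate dehydrogenase LDHA at 0.24 ± 0.50, with adjusted p of 0.89, 0.962 and 0.909. ALDOC, an aldolase, was at 1.89 ± 0.85, and the lactate transporter SLC16A1 at -0.61 ± 0.31. The values of the list, SLC2A1, HK2 and LDHA rested on high replicate 3: without it the list stood at -0.01, SLC2A1 at -0.18, HK2 at -0.54 and LDHA at -0.05, while without high replicate 6 the list passed (0.40, adjusted p = 0.0213, within a range of 0.0213 to 0.998 over the alternatives). Hypoxia targets were higher in 25 of 28 members, with a median of 0.79 (adjusted p = 0.00118; 0.809 with an estimated correlation), a median that fell to 0.41 without high replicate 3 and a call that ended without high replicates 1 to 3 (0.30). Nuclear-encoded respiratory chain genes were higher in 29 of 37 (median 0.40, adjusted p = 1.54e-04; 0.809 with an estimated correlation), with UQCRB at 0.97 ± 0.34 and COX4I1 at 0.73 ± 0.28. Correction for GC content and length lowered that median to 0.07 and ended the call, with biopsy position in the fit it was 0.16, and without high replicate 5 it was 0.25. The pentose phosphate (0.27, adjusted p = 0.12), citric acid cycle (0.07, 0.687) and fatty acid oxidation lists (0.27, 0.198) did not pass. Targets of ATF4, the regulator of amino acid synthesis, had a median of -0.20 (adjusted p = 0.0524), with PSAT1 and ASNS both at -1.39 ± 0.28. That list passed without low replicate 1 (adjusted p = 0.0245), without high replicate 1 (0.0101) or without high replicate 3 (0.0121), within a range of 9e-04 to 0.874.

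NF-kB-driven inflammatory genes were higher in 23 of 26 members, with a median of 1.14 (adjusted p = 8.28e-04; 0.804 with an estimated correlation), and the call ended at a stricter expression filter (0.78). The mean log2 CPM of the list was 3.706 in high replicate 1 and 2.465 to 2.837 in high replicates 2, 3, 4 and 6. In high replicate 5 it was 1.952, below the 2.216 and 2.041 of the low biopsies. The chemokine CCL20, at 0.29 and 0.219 CPM in the low biopsies, was at 2.15 ± 1.84 CPM in the high constructs. Genes induced by laminar flow were lower in 11 of 16 members, with a median of -0.38 (adjusted p = 0.0025; 0.679 with an estimated correlation). The smallest p of all genes belonged to one of them, ASS1, an enzyme of arginine synthesis, at 17.8 and 10.4 CPM in the low biopsies and 2.61 ± 0.32 CPM in the high constructs (-2.40 ± 0.30). THBD, the anticoagulant receptor thrombomodulin, was at -1.02 ± 0.35 (-1.33 to -0.66 with 1 library left out) and the flow-responsive transcription factor KLF2 at -0.38 ± 0.50. Without low replicate 1 the laminar flow list stood at -0.13 and did not pass, and KLF2 stood at 0.10, whereas without low replicate 2 the list stood at -0.65. Nor did the list pass with biopsy position in the fit (-0.24).

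Endothelial identity lists did not pass: the pan-endothelial list had a median of -0.12 (adjusted p = 0.494; 0.07 without low replicate 1), the liver sinusoidal list 0.14 (0.472), the arterial and Notch list 0.47 (0.472), the venous and lymphatic list 0.10 (0.472) and the tip cell list 0.11 (0.627). VWF, the von Willebrand factor, was at 4943 and 4159 CPM in the low biopsies against 2016 ± 354 CPM (-1.15 ± 0.27, adjusted p = 0.513). LYVE1, the hyaluronan receptor of sinusoidal and lymphatic endothelium, was at 79.3 and 78.4 CPM against 224 ± 82.6 CPM (1.53 ± 0.50, adjusted p = 0.574). The junction genes PECAM1 and CDH5 were at 0.26 ± 0.35 and -0.25 ± 0.28, and the VEGF receptor KDR at 0.16 ± 0.43 (-0.06 without high replicate 6). Other single values were SELP at -2.07 ± 0.57, DARC at -1.89 ± 0.32, STAB1 at -1.12 ± 0.35, the Notch ligand JAG1 at -0.89 ± 0.25, PDGFB at -0.81 ± 0.25 and LXN at 1.41 ± 0.28. None of the following lists passed either: YAP targets (-0.13, adjusted p = 0.0555; AXL at -1.41 ± 0.44), basement membrane (-0.26, 0.0555), BMP targets (0.13, 0.52), mesenchymal transition (0.18, 0.187), cholesterol synthesis (-0.02, 0.472), unfolded protein response (0.15, 0.472), heat shock (0.16, 0.472), immediate early genes (0.59, 0.472), nuclear noncoding RNA (-0.21, 0.472) and replication histones (-0.29, 0.254). Anticoagulant and procoagulant genes had medians of 0.12 (adjusted p = 0.978) and -0.25 (0.326). The test direction was down for the anticoagulant and the venous lists, whose means were 0.14 and -0.01, and the procoagulant list had a mean of 0.02 against a negative median.

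**Figure D2:**
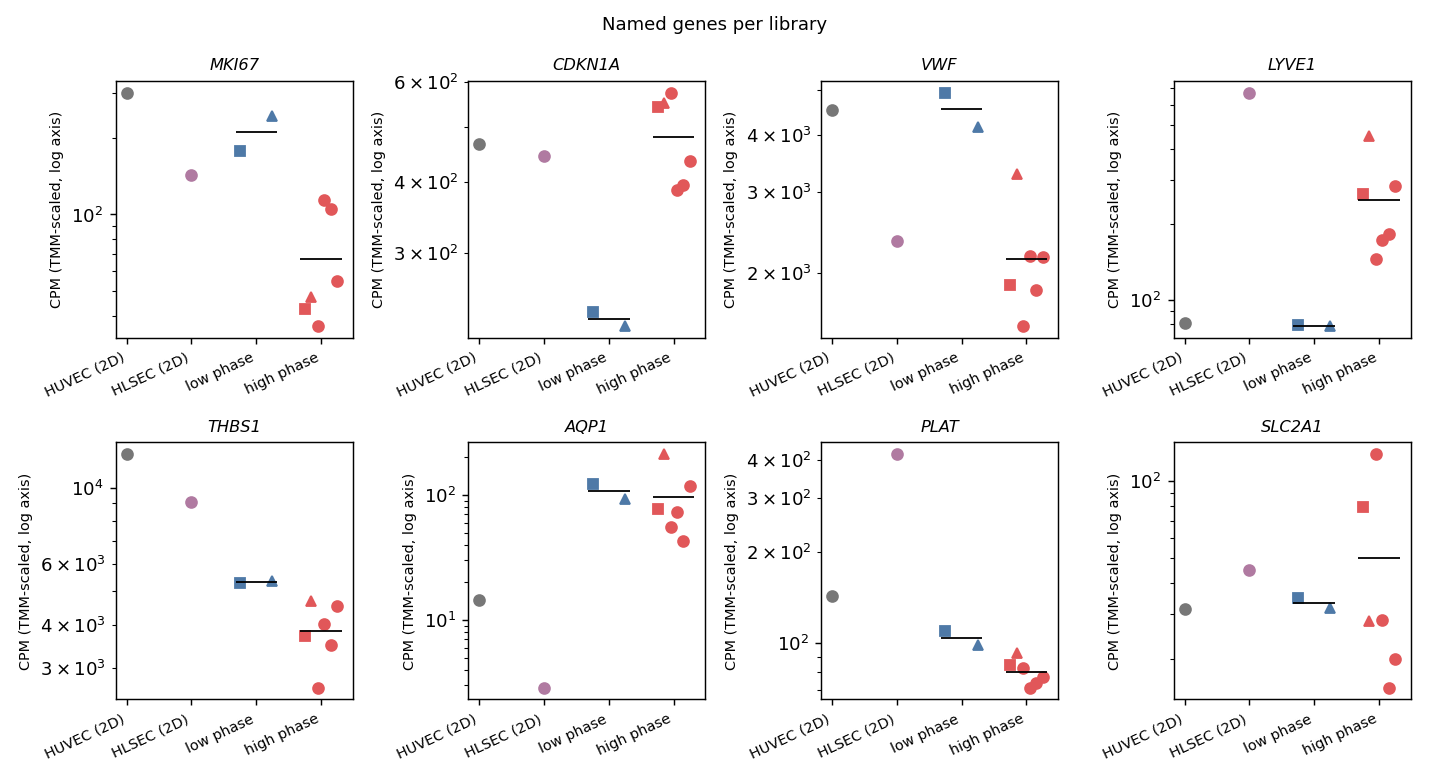
CPM (TMM-scaled, logarithmic vertical axis) of MKI67, CDKN1A, VWF, LYVE1, THBS1, AQP1, PLAT and SLC2A1 in each of the 10 libraries by group (horizontal axis), each point being 1 library. VWF was at 4943 and 4159 CPM in the low biopsies and at 2016 ± 354 CPM (SD) over the 5 high constructs.

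Among markers of other cell types, albumin (ALB) had 0 to 6 counts per library and the leukocyte marker PTPRC 0 to 2, and HBB reached 2. Others were present in every group: the mural gene RGS5 had 45616 to 192900 counts, the epithelial keratin KRT19 170 to 7736 and the macrophage gene CD68 1396 to 5864, in cultured cells as in constructs. Of the hepatocyte list 5 of 15 members were expressed enough for testing, and against the low construct their median was -0.43 with a mean of 0.18 (adjusted p = 0.687). Epithelial genes had a median of -0.09 and a mean of 0.03 (adjusted p = 0.899, test direction down), mural genes 0.08 and -0.01 (0.768) and fibroblast or stellate genes 0.75 (0.472). The leukocyte list kept 4 genes, too few for a test, with a median of 0.35, and the erythroid and mitochondrial genome lists kept 0. Fibrillar collagen COL1A1 had 0 to 38 counts in each library, whereas COL1A2 had 10782, 19246 and 19614 counts in high replicates 1, 2 and 6, against 1958 to 4682 in the other high biopsies and 2142 and 1524 in the low ones. At far lower counts, PDGFRA (84, 76 and 114 against 12 to 16) and COL3A1 (176, 270 and 356 against 28 to 82) followed COL1A2 in the high biopsies. The sinusoidal scavenger receptor STAB2 stayed at 2 to 16 counts per library.

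The comparison of high constructs with cultured HUVEC asked how the seeded cells differed from the same cell type on plastic. In the high constructs cell cycle, YAP target, basement membrane and cholesterol synthesis genes were lower, and ribosomal protein and laminar flow genes were higher. These list calls were all lost with an estimated correlation, with an adjusted p of 0.194 for YAP targets, 0.908 for cholesterol synthesis and 0.635 for the others. The matrix glycoprotein thrombospondin 1 (THBS1) was at 12499 CPM in HUVEC and at 3717 ± 722 CPM in the 5 high constructs (-1.76 ± 0.27, adjusted p = 0.0707), and MKI67 was at 301 against 70.2 ± 35.8 CPM (-2.10 ± 0.51, adjusted p = 0.165). The water channel AQP1, a flow-induced gene, was at 14.5 against 84.1 ± 39.7 CPM (2.53 ± 0.68, adjusted p = 0.21). Of 16496 genes, 1 was higher and 5 were lower. CCDC69 (hg19, chromosome 5, 150560613 to 150603654) rose from 13.2 to 95.6 ± 10.9 CPM (2.85 ± 0.33, adjusted p = 0.0306). The imprinted gene MEST (chromosome 7, 130126016 to 130146138) fell from 37.9 to 5.49 ± 1.23 CPM (-2.79 ± 0.30, adjusted p = 0.0302). The other 4 lower genes were chosen after their values were seen: LYPD1 at -4.10 ± 0.42, SLC30A3 at -3.83 ± 0.45, C4orf49 at -3.57 ± 0.32 and WNK4 at -3.31 ± 0.39. Unadjusted p under 0.05 was reached by 841 higher and 1130 lower genes, and DESeq2 called 170 higher and 207 lower. All 6 calls ended without high replicate 3 (adjusted p from 0.0792 to 0.103) and without high replicate 4 (from 0.105 to 0.165), and leaving out high replicate 6 raised the counts to 3 higher and 31 lower. SLC30A3 also lost its call without high replicate 1 (0.0595). Without high replicate 5, 0 were higher and 3 lower, without high replicate 1 the count of higher genes was 2, and with a stricter filter no gene passed.

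As in the comparison with the low construct, ribosomal protein genes were higher in all 34 members (median 1.01, adjusted p = 3.06e-20; 27 higher when adjusted over the list alone), beside a ribosomal protein share of 10.4% to 15.2% in the 6 high biopsies and 6.2% in HUVEC. RPS14 was at 1.32 ± 0.34. All 26 G2/M genes (median -1.32, adjusted p = 1e-16; 4 when adjusted over the list alone) and all 27 S phase genes (median -1.14, adjusted p = 2.26e-15; 11 when adjusted over the list alone) were lower, with the DNA polymerase subunit POLA1 at -1.48 ± 0.36 and MCM4 at -1.89 ± 0.43. Laminar flow genes were higher in 13 of 16 (median 1.17, adjusted p = 4.41e-04), KLF2 standing at 1.65 ± 0.59 and ASS1 at 1.47 ± 0.40. Basement membrane genes were lower in 12 of 15 (median -0.37, adjusted p = 4e-06), with the network collagen COL8A1 at -2.21 ± 0.35 and the heparan sulfate proteoglycan HSPG2 at -1.95 ± 0.40, and the median was -0.64 without high replicate 3 and -0.68 without high replicate 4. Procoagulant genes were lower in 6 of 8 (median -0.89, adjusted p = 0.00144), including THBS1 and VWF (-1.17 ± 0.27). With an estimated correlation each of these 6 lists had an adjusted p of 0.635. YAP targets were lower in 17 of 21 (median -0.64, adjusted p = 4.08e-06; adjusted p = 0.194 with an estimated correlation, and 0.0103 by fry), among them CYR61 at -2.41 ± 0.41 and CRIM1 at -1.80 ± 0.29. Cholesterol synthesis genes were lower in 22 of 23 (median -0.52, adjusted p = 2.44e-05; 0.908 with an estimated correlation), with DHCR7 at -1.45 ± 0.47, and their median was -1.06 without high replicate 5. CYR61, CRIM1, COL8A1, THBS1, PDGFB (-1.56 ± 0.24, adjusted p = 0.0684) and CDH2 (-1.77 ± 0.30, adjusted p = 0.078) passed without high replicate 6 (adjusted p from 0.0329 to 0.0463).

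Further lists passed with smaller margins. Respiratory chain genes were higher in 31 of 37 (median 0.38, adjusted p = 0.00249; 0.91 with an estimated correlation), with COX6B1 at 0.98 ± 0.32. That call ended without high replicate 5 (median 0.18) and with the GC content and length correction (0.04). Heat shock genes were lower in 13 of 17 (median -0.37, adjusted p = 0.00933; 0.685 with an estimated correlation), although their mean was 0.06 and their median -0.62 without high replicate 1, with HSP90AA1 at -1.06 ± 0.35. Interferon-stimulated genes were higher in 23 of 29 (median 0.61, adjusted p = 0.0176; 0.91 with an estimated correlation; 0.50 and not past the threshold without high replicate 6), with IFI27 at 1.12 ± 0.32. Tip cell genes were lower in 13 of 23 (median -0.34, adjusted p = 0.0219; 0.685 with an estimated correlation; not past it without high replicate 5, -0.32; median -0.21 without high replicate 4). Hypoxia genes were higher in 23 of 28 (median 0.66, adjusted p = 0.024; 0.91 with an estimated correlation), with PDK1 at 1.08 ± 0.44 and the collagen cross-linking enzyme LOXL2 at -1.10 ± 0.34. The hypoxia call ended without high replicate 1 (0.60) or 3 (0.34). Chaperones of the unfolded protein response were lower in 15 of 20 (median -0.31, adjusted p = 0.0245; 0.91 with an estimated correlation), with PDIA6 at -0.84 ± 0.25, and did not pass without high replicate 4 (-0.25) or 5 (-0.27).

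The glycolysis list had a median of 0.16 against HUVEC (adjusted p = 0.884), with SLC2A1 at 0.62 ± 0.99, HK2 at -0.54 ± 0.79 and LDHA at 0.17 ± 0.49. Without high replicate 3 the list stood at -0.09, SLC2A1 at -0.13 and LDHA at -0.12. HK2 ranged from -1.255 to -0.332 when 1 library was left out. Other metabolic lists did not pass: pentose phosphate (0.06, adjusted p = 0.934), ATF4 targets (0.17, 0.897), citric acid cycle (-0.14, 0.629) and fatty acid oxidation (0.07, 0.884). Nor did the endothelial lists: pan-endothelial (0.10, 0.898; mean 0.05 with test direction down), liver sinusoidal (0.87, 0.12), arterial (0.02, 0.729; mean 0.09 with test direction down) and venous (0.36, 0.466). LYVE1 was at 80.7 CPM in HUVEC (1.47 ± 0.50, adjusted p = 0.291), PECAM1 at 0.54 ± 0.36, CDH5 at -0.73 ± 0.27 and KDR at -0.40 ± 0.42. The same held for BMP targets (0.46, 0.854), p53 targets (0.07, 0.854), NF-kB genes (0.47, 0.934), anticoagulant genes (0.53, 0.753), mesenchymal transition (0.09, 0.934), immediate early genes (0.24, 0.854; test direction down), NRF2 targets (0.06, 0.897), nuclear noncoding RNA (-0.01, 0.898) and replication histones (-0.39, 0.35). Among markers of other cell types, the hepatocyte (1.48, 0.0891), epithelial (0.34, 0.629), mural (0.26, 0.934) and fibroblast lists (0.84, 0.35) did not pass, and the 4 leukocyte genes had a median of 0.83.

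**Figure D3:**
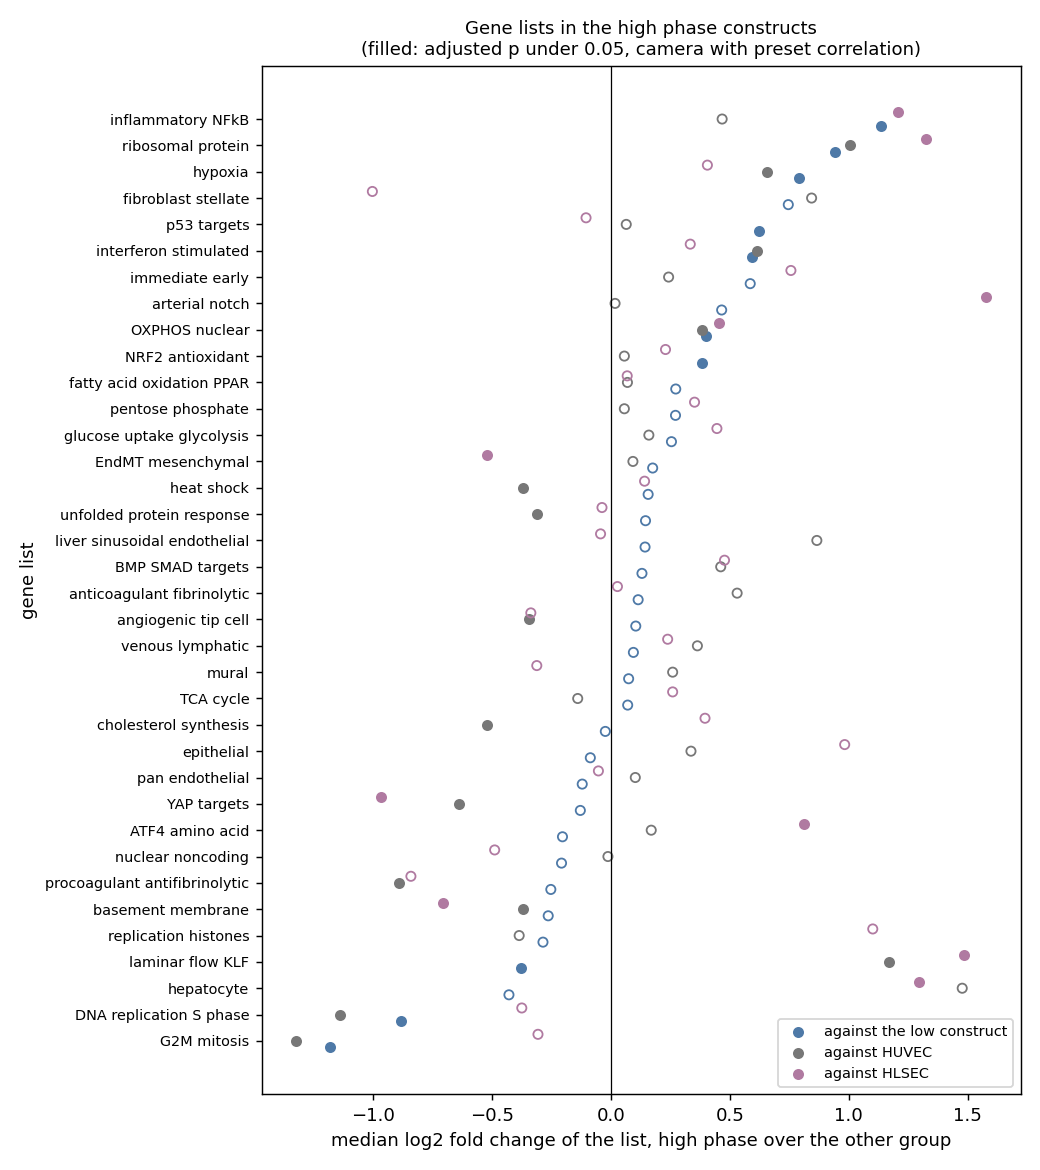
Median log2 fold change (horizontal axis) of each tested gene list (vertical axis) in the high constructs against the low construct, HUVEC and HLSEC; filled points had an adjusted p under 0.05 by camera with its preset correlation and open points did not. Ribosomal protein genes were higher in all 3 comparisons, with medians of 0.94, 1.01 and 1.33, and with an estimated correlation no list passed in any of them.

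Against HLSEC, the comparison with primary endothelium of the liver, the high constructs differed in 233 higher and 584 lower genes. PLAT, the tissue plasminogen activator (hg19, chromosome 8, 42032236 to 42065194), fell from 420 to 77.4 ± 5.99 CPM (-2.45 ± 0.21, adjusted p = 3.4e-04). BCHE, butyrylcholinesterase, fell from 75.8 to 0.569 ± 0.349 CPM (-7.07 ± 0.54, adjusted p = 2.4e-04). The endothelial diaphragm protein PLVAP rose from 0.694 to 36.8 ± 17.1 CPM (5.71 ± 0.92, adjusted p = 0.00772), and AQP1 from 2.88 to 84.1 ± 39.7 CPM (4.85 ± 0.80, adjusted p = 0.00858). Donor tissue and growth format both differed between these groups. At an unadjusted p under 0.05 the counts were 1214 and 1691, and DESeq2 called 618 genes higher and 760 lower. Without high replicate 4 the counts were 116 and 350, without high replicate 6 they were 342 and 710, and a stricter filter gave 97 and 227.

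The largest increases included the protease TLL1 at 7.48 ± 0.99, the amino acid transporter SLC38A5 at 7.23 ± 0.72 and HIF3A at 6.73 ± 0.91. For genes with 0 to 3 read pairs in a group, ratios of summed counts were used. The prostaglandin transporter SLCO2A1 was 769-fold higher (counting interval 213 to 6348), THY1 198-fold (67.6 to 959) and DARC 126-fold (22.5 to 4977), while periostin (POSTN), without a count in HLSEC, was at least 208-fold higher. AMTN was 18520-fold lower (3321 to 731500), although DESeq2 left it at an adjusted p of 0.0635, the highest over the alternatives (lowest 3.7e-07). CLEC4M, a C-type lectin of liver sinusoidal endothelium, had 172 counts in HLSEC and 0 in every other library, and was at least 162-fold lower. Further decreases were found for the lipoprotein receptor LRP1 (-5.35 ± 0.70), COL12A1 (-4.70 ± 0.46), the metalloproteinase MMP10 (-4.69 ± 0.42), CELSR1 (-4.44 ± 0.39), the noncoding RNA MEG3 (-2.97 ± 0.58) and the heme-degrading enzyme HMOX1 (-2.33 ± 0.28).

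By list, ribosomal protein genes were higher in all 34 members (median 1.33, adjusted p = 7.73e-18), with 7 called and 34 passing when adjusted over the list alone, beside a ribosomal protein share of 5.3% in HLSEC. RPL11 (1.46 ± 0.32) and RPL5 (1.46 ± 0.31) were among the 7 and lost their calls without high replicate 1, 3 or 4. ATF4 targets were higher in 16 of 18 (median 0.81, adjusted p = 0.00374), led by PHGDH, the first enzyme of serine synthesis, which rose by 4.51 ± 0.57. Respiratory chain genes were higher in 34 of 37 (median 0.46, adjusted p = 0.00897), but at 0.26 without high replicate 5 and at -0.02 after the GC content and length correction. NF-kB genes were higher in 19 of 26 (median 1.21, adjusted p = 0.0341), none called singly, with IL8 at -2.43 ± 0.65, and the call ended without an expression filter (adjusted p = 0.154, the highest over the alternatives). Basement membrane genes were lower in 11 of 15 (median -0.70, adjusted p = 0.00376), with falls in NID2 (-3.23 ± 0.43) and HSPG2 (-2.18 ± 0.40). With an estimated correlation the adjusted p of these 5 lists was 0.868. Mesenchymal transition genes were lower in 12 of 16 (median -0.52, adjusted p = 0.00897; 0.669 with an estimated correlation and 0.0484 by fry), with N-cadherin CDH2 down by a log2 fold change of -1.88 ± 0.30. YAP targets were lower in 15 of 21 (median -0.97, adjusted p = 0.0136; 0.669 with an estimated correlation and 0.0182 by fry), though IGFBP3 rose by 6.45 ± 0.87. That call ended with the GC content and length correction (-0.76).

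The arterial and Notch list (median 1.58, 11 of 15 higher, adjusted p = 0.046), the laminar flow list (1.49, 12 of 16, 0.046) and the hepatocyte list (1.30, 5 of 5, 0.0479) passed narrowly, and with an estimated correlation their adjusted p was 0.868. Without high replicate 2 all 3 missed the threshold (adjusted p = 0.0526). Without high replicate 6 the arterial list (0.0642) and the hepatocyte list (0.0695) did too, the latter also without high replicate 1 (0.0502) or 3 (0.0623). Over all alternatives the adjusted p ranged from 8.7e-04 to 0.207 for the arterial, 0.0086 to 0.146 for the laminar flow and 0.0086 to 0.471 for the hepatocyte list. Of the hepatocyte genes, APOB was called, at 0.36 CPM in HLSEC and 4.31 ± 1.24 CPM in the high constructs (3.56 ± 0.60). Within the laminar flow list AQP1 rose and HMOX1 fell. The receptor NOTCH4 was at 2.08 and lost its call without high replicate 1, 3 or 4 (highest adjusted p = 0.0938, within 2.4e-04 to 0.0938).

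Endothelial lists were split: pan-endothelial genes had a median of -0.05 and a mean of 0.34 (adjusted p = 0.628) and liver sinusoidal genes a median of -0.04 (0.302; 0.41 without high replicate 2 and 0.10 without high replicate 5). Of the 19 sinusoidal genes 13 were tested. By its median, this list hardly differed between HLSEC itself and HUVEC (median log2 ratio 0.08, percentile 72.63 of matched random lists, 8 of 13 members higher in HLSEC). Single members did differ: LYVE1 had 52150 counts in HLSEC and 6694 in HUVEC, CLEC4M 172 and 0, and DNASE1L3 2 and 46. A median near 0 is therefore no measure of likeness to sinusoidal endothelium. Within that list CLEC4M and CRHBP (40 counts in HLSEC and 0 to 4 in each high biopsy) fell. DNASE1L3, at 1 read pair in HLSEC, was 55-fold higher (counting interval 9.79 to 2178), and FCN3, a lectin of the complement system, was higher by 4.01 ± 0.84. The CRHBP call was lost without high replicate 1, 3 or 4 (highest adjusted p = 0.0732, within 0.0181 to 0.0864) and that of FCN3 without high replicate 4 (0.0599, within 5.9e-06 to 0.0672). CDH5 fell from 2046 to 961 ± 150 CPM (-1.11 ± 0.26, adjusted p = 0.0455), a call lost without high replicate 1, 3 or 4 (highest 0.106, within 0.0149 to 0.198 over the alternatives). LYVE1 was at 670 CPM in HLSEC (-1.60 ± 0.40, adjusted p = 0.0525), and passed without high replicate 2 (0.0204) or 6 (0.0327), within 0.0117 to 0.143. VWF was at -0.23 ± 0.29, PECAM1 at 0.22 ± 0.35, KDR at -0.59 ± 0.41, MKI67 at -1.04 ± 0.54 and KLF2 at 1.82 ± 0.60 (past the threshold without high replicate 6). Venous (0.24, adjusted p = 0.299), tip cell (-0.34, 0.299) and BMP lists (0.48, 0.467) did not pass. In fibrinolysis and coagulation, PLAU fell with PLAT (-1.69 ± 0.31), while the list medians of 0.03 for anticoagulant (test direction down, adjusted p = 0.315) and -0.84 for procoagulant genes (0.0751) did not pass. THBS1 was at -1.30 ± 0.28 and lost its call without high replicate 1 or 4.

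Glycolysis genes did not pass against HLSEC (median 0.45, adjusted p = 0.588), with SLC2A1 at 0.11 ± 0.95, HK2 at 0.48 ± 0.86 and LDHA at 0.65 ± 0.51. Without high replicate 3, SLC2A1 stood at -0.63 and HK2 at -0.22, and without high replicate 1 SLC2A1 stood at -0.06. Cell cycle lists, which passed against HUVEC, did not pass here (S phase -0.37, adjusted p = 0.107; G2/M -0.31, 0.299). The remaining lists did not pass: pentose phosphate (0.35, 0.279), citric acid cycle (0.26, 0.295), fatty acid oxidation (0.07, 0.663, test direction down), hypoxia (0.41, 0.407), p53 targets (-0.10, 0.739), interferon-stimulated genes (0.33, 0.279), cholesterol synthesis (0.40, 0.532), unfolded protein response (-0.04, 0.972; mean 0.07), heat shock (0.14, 0.739), immediate early genes (0.76, 0.545), NRF2 targets (0.23, 0.893), nuclear noncoding RNA (-0.49, 0.545) and replication histones (1.10, 0.295). Markers of other cell types gave medians of 0.98 for epithelial (0.0567), -0.31 for mural (0.279), -1.002 for fibroblast genes (0.549; mean 0.72, test direction down) and -0.01 for the 4 leukocyte genes (mean 0.43).

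Proximal and distal biopsies of the same construct were compared to see how far position mattered, over 4 libraries of 2 constructs with 1 residual degree of freedom. The genes lower in the distal biopsies included the nuclear receptors NR4A2 and NR4A1 and the chemokines CXCL1 and CCL20, and for each the ratio lay further below 0 in the high construct. No gene list entered a test of position over both constructs. Of 15272 genes, 0 were higher and 11 lower, against 227 and 239 at an unadjusted p under 0.05; DESeq2 called 0 higher and 1 lower. The nuclear receptor NR4A2 fell by 3.16 ± 0.39 on the log2 scale (adjusted p = 6.65e-06), with a distal over proximal ratio of -0.78 in the low and -3.65 in the high construct. EGLN3, a hypoxia-induced prolyl hydroxylase, was at -2.46 ± 0.42 (adjusted p = 0.00463; -0.08 and -2.74 in the respective constructs), and the heat shock protein HSPA1A at -1.77 ± 0.36 (0.0255; -0.13 and -3.30), whose near-identical copy HSPA1B, also called, can share its reads. For NR4A2, EGLN3 and HSPA1A the constructs lay much further apart than the SE. Their calls therefore do not show a position effect shared by both constructs. The other lower genes were NR4A1 (-1.46 ± 0.27), CRYAB (-3.63 ± 0.68), CXCL1 (-1.54 ± 0.30), CCL20 (-2.43 ± 0.48), G0S2 (-1.31 ± 0.26), the NF-kB inhibitor TNFAIP3 (-1.28 ± 0.26) and INA (-3.14 ± 0.67). Of these 11, HSPA1A and G0S2 met the naming rule and the others were chosen after their values were seen. SELE was at -1.89 ± 0.41 (adjusted p = 0.0524) and DNAJB1 at -0.91 ± 0.25. The largest positive values belonged to A2M and FAM198B (both 0.72), ATP2B1 (0.71) and SGMS2 (0.66), none past the threshold. SLC2A1 was at -0.83, HK2 at -0.71, LDHA at -0.28, MKI67 at 0.29, VWF at 0.26, LYVE1 at 0.36, KLF2 at -0.21, PECAM1 at 0.04, CDH5 at -0.10 and KDR at 0.24.

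**Figure D4:**
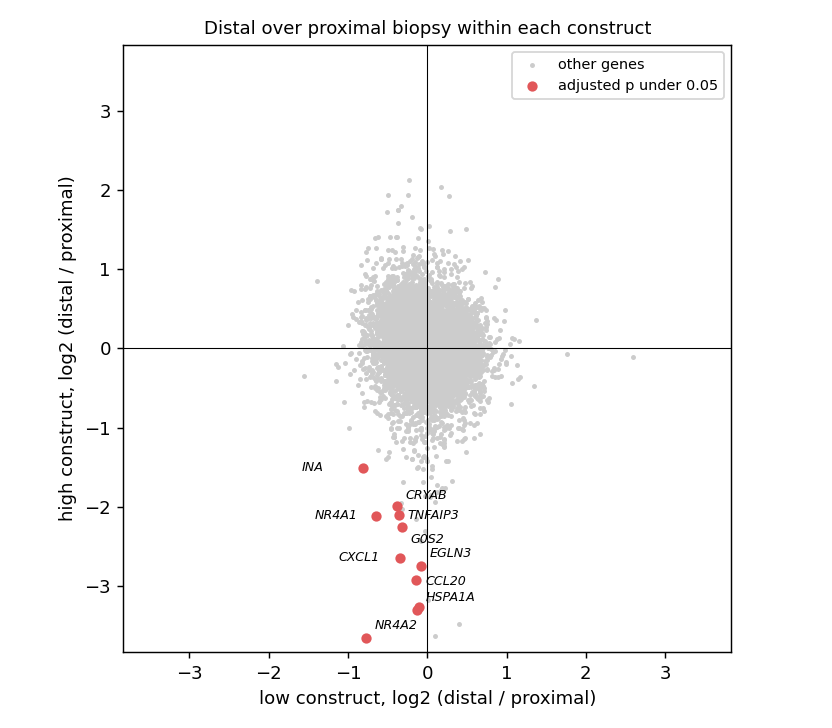
Log2 ratio of the distal over the proximal biopsy in the low construct (horizontal axis) and in the high construct (vertical axis); each point is 1 of 15272 genes, and red points had an adjusted p under 0.05 by edgeR. NR4A2 had ratios of -0.78 and -3.65 and HSPA1A of -0.13 and -3.30.

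Without replicates, the low construct and HLSEC were each compared with HUVEC as log2 ratios of CPM + 0.5, which describe these libraries alone. Relative to HUVEC, the low construct held more of the matrix protein fibulin 2 (FBLN2, 6.39), SLCO2A1 (3.77), AQP1 (2.82) and HSPA12B (2.48), and less of the stretch-activated channel PIEZO2 (-3.37), COL12A1 (-2.58), CCNA1 (-2.24) and FBN2 (-1.91). KLF2 stood at 1.97 and the laminar flow list at a median of 1.37, above all of 10000 random lists matched on expression. Genes of the random lists were drawn independently, so a list whose members vary together can fall outside all of them. The position of a list among them is therefore no test of that list. VWF (-0.03), LYVE1 (-0.06), LDHA (-0.07) and SLC2A1 (0.05) lay near 0, PECAM1 was at 0.28, CDH5 at -0.48, KDR at -0.56, MKI67 at -0.54 and HK2 at -0.71. HLSEC held more LYVE1 (3.06), BCHE (5.72), KCNMA1 (4.57) and PTGS1 (3.76) than HUVEC, and AMTN had 3272 read pairs against 1 in HUVEC (interval of the log2 ratio 9.30 to 17.08). CYTL1 (-6.68), LIPG (-4.47), ALPK3 (-4.34) and CCNA1 (-3.65) were lower. VWF was at -0.94, MKI67 at -1.06, HK2 at -1.001, LDHA at -0.48, SLC2A1 at 0.51, CDH5 at 0.37, PECAM1 at 0.33, KDR at 0.19 and KLF2 at -0.17.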

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

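The use of all tests in this paragraph on this pattern was chosen after the result was seen, although scaling by library totals had been planned as an alternative. The lower G2/M and S phase genes of the high constructs, with a joint median of -1.146 against the low construct, were weighed against technical causes. Removing the GC content and length trend left a median of -1.228 (interval over list members -1.278 to -1.055), so that trend does not account for it. Scaling by library totals left -1.351 (-1.397 to -1.189). Both intervals treat members as independent, although the estimated correlation was 0.915 for G2/M and 0.831 for S phase. They do not cover spread between constructs. Library totals also lowered the median over all genes, from 0.048 to -0.134, so they could only lower the lists further. They cannot decide whether a few abundant genes shifted the scaling. The RNA extraction solution remains possible against the low construct, because 0 low libraries shared the solution of the high ones. HUVEC did share it by its label, so the solution did not differ in that comparison.

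The tests of the ribosomal protein genes were also chosen after the result was seen. Removing the GC content and length trend lowered their median against the low construct from 0.942 to 0.671 (interval over list members 0.575 to 0.741). The trend may thus account for a part of the difference in these libraries and not for all. Again 0 low libraries shared the extraction solution of the high ones, which leaves that cause open. HUVEC and HLSEC carried the same solution label as the high biopsies, so the solution did not differ in those comparisons.

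For the stress and inflammatory genes that were higher in the proximal biopsy of the high construct, the tests were likewise chosen after the result was seen. A position effect common to both constructs could be weighed by the low construct. Its median ratio was -0.114 (interval over list members -0.186 to -0.036) against -0.557 in the high one. Leukocytes in the proximal biopsy were not a likely source, since 5 leukocyte genes had 6 counts there together and IL8 alone had 3264. What set that biopsy apart was not resolved.

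Single libraries that stood apart from the other high constructs were sought in 145 tests, of which chance marks about 1 in 20, and 10 stood out. High replicate 5 had 317.6 CPM of UQCRB (200.3 to 219 in the others) and 1108 CPM of HSP90AA1 (578.8 to 655.7). Its mean log2 CPM was 6.317 for cholesterol synthesis genes (4.834 to 5.209) and 0.05236 for hepatocyte genes (0.6086 to 0.7465). High replicate 3 had 77.83 CPM of HK2 (11.78 to 24.63), 35.03 of MXI1 (12.5 to 17.76) and 492.5 of GAS5 (275.5 to 329.4). High replicate 6 had 15.11 CPM of COL12A1 (4.816 to 7.368) and 0.02727 of AMTN, which was at 0 in the others. The AMTN mark rested on 1 read pair and carries no information, since any lone value above 0 is marked whatever its size. The construct of high replicates 1 and 2 had 7.617 CPM of MEST (4.531 to 5.403). The distal over proximal ratio had opposite signs in the low and the high construct, without a test, for SELE (0.091 and -3.623), DNAJB1 (0.041 and -1.848), A2M (-0.096 and 1.524), LDHA (0.17 and -0.72), VWF (-0.248 and 0.757), PECAM1 (-0.2 and 0.288), CDH5 (-0.225 and 0.034), LYVE1 (-0.014 and 0.727) and KLF2 (-0.822 and 0.406).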

How the results depend on the processing

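The comparisons rest on 1 low construct, 1 HUVEC and 1 HLSEC library, and low biopsies differed from all others in extraction solution. The main tests called 0 higher and 0 lower genes against the low construct, 1 and 5 against HUVEC, 233 and 584 against HLSEC, and 0 and 11 between distal and proximal biopsies, and 10, 14 and 10 lists. Halved counts, the GC content and length correction, leaving out high replicates 1 to 3 and the unblocked fit were chosen after the data were seen. The alternative without mitochondrial genes was not run. Library totals moved the median over all genes against the low construct from 0.048 to -0.134. Values of named genes were tallied by sign and by their side of the 0.05 threshold, or by the counting interval for ratios without replicates. Of these, 2933 stayed the same, 156 became weaker, 160 stronger, 29 reversed and 57 moved. A value tallied as the same can still differ in size. With 1 library left out, MKI67 against the low construct ranged from -1.819 to -1.328 and was tallied as the same throughout. The values that moved were ratios without replicates that left their counting intervals. Over the list medians, tallied in the same way or by sign alone where a setting gave no list test, 772, 50, 11 and 18 stayed, weakened, strengthened or reversed. Counts of called genes are outside this tally and are given below. The cause of these shifts was not tested.

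For lists, camera with an estimated correlation passed 0, 0 and 0 against the low construct, HUVEC and HLSEC, and fry 0, 1 and 2. Against HLSEC, no filter and each library as a sample each passed 6. With each library as a sample, 137 genes were higher and 205 lower against the low construct, 24 and 113 against HUVEC and 439 higher against HLSEC, and the pan-endothelial list stood at 0.03 against HLSEC. DESeq2 called 25 and 43, 170 and 207, and 618 higher, in the same order. RLE scaling and library totals each gave 2 higher genes against HUVEC. Library totals set HK2 at -0.044 against the low construct and, relative to HUVEC, VWF at 0.124 and LDHA at 0.075 in the low construct, where VWF was at 0.117 without low replicate 2. No filter gave 4 and 28 genes against HUVEC, and the stricter filter 0 and 0 there and 97 and 227 against HLSEC. A test against a 1.5-fold change gave 147 and 347 against HLSEC. Between distal and proximal biopsies the stricter filter called 6 lower, DESeq2 1, halved counts 17 lower and 2 higher, and RLE 2 higher. limma with voom set HK2 at -0.19 against the low construct.

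With the replicate number as a block over replicates 1 and 2 of both phases, 1926 genes were higher and 2089 lower, and without the block 2022 and 2134. These fits compare biopsies of 1 low with biopsies of 1 high construct and rest on the spread within constructs (0.13 and 0.181, against 0.304 between high constructs), while the fit over constructs called 0. The numbers mark biopsy position and link nothing else, and deviations with the same number had a Pearson correlation of -0.204 and a Spearman correlation of -0.242 over 11794 genes. The block set HK2 at -0.347, LDHA at -0.042 and the pan-endothelial list at 0.079, and the unblocked fit set them at -0.192, 0 and 0.154. With biopsy position in the fit HK2 was at -0.306, CDH5 at 0.04 and the pan-endothelial list at 0.123. The GC content and length correction gave 6 and 12 genes against HUVEC, set the pan-endothelial list at 0.014 against the low construct and, against HLSEC, respiratory chain genes at -0.023, VWF at 0.136, the liver sinusoidal list at 0.121 and the pan-endothelial list at 0.128.

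Leaving out 1 library at a time gave 0 to 3 higher and 0 to 31 lower genes against HUVEC, and 116 to 342 and 350 to 710 against HLSEC. Over these runs, against the low construct, the glycolysis list ranged from -0.007 to 0.401, SLC2A1 from -0.178 to 0.774, HK2 from -0.54 to 0.383, LDHA from -0.046 to 0.401, the pan-endothelial list from -0.259 to 0.069, KLF2 from -0.762 to 0.098 and KDR from -0.058 to 0.268. Against HUVEC the glycolysis list ranged from -0.092 to 0.279, SLC2A1 from -0.126 to 0.825 and LDHA from -0.118 to 0.328. Against HLSEC the liver sinusoidal list ranged from -0.25 to 0.409, SLC2A1 from -0.627 to 0.321 and HK2 from -0.223 to 0.684. VWF in the low construct relative to HUVEC ranged from -0.162 to 0.117. Without high replicate 3, SLC2A1, HK2, LDHA and the glycolysis list stood at -0.178, -0.54, -0.046 and -0.007 against the low construct. SLC2A1, LDHA and the list stood at -0.126, -0.118 and -0.092 against HUVEC, and SLC2A1 and HK2 at -0.627 and -0.223 against HLSEC. Without high replicates 1 to 3 they stood at -0.645, -0.702, -0.076 and -0.02 against the low construct, at -0.562, -0.117 and -0.117 against HUVEC and at -1.066 and -0.357 against HLSEC. That setting gave 3 and 10 genes against HUVEC, and set the liver sinusoidal list at 0.227 and the pan-endothelial list at 0.02 against HLSEC. Without low replicate 1 KLF2 was at 0.098 and the pan-endothelial list at 0.069, and without high replicate 6 KDR was at -0.058. Against HLSEC, SLC2A1 was at -0.058 without high replicate 1, and the liver sinusoidal list at 0.409 without high replicate 2, 0.101 without high replicate 5 and 0.378 without the construct of replicates 1 and 2. Without that construct 0 genes were higher and 3 lower against HUVEC.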

Other observations

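COL1A2 was at 2.23 ± 1.30 against the low construct, POSTN at 2.10 ± 1.15 and THY1 at 1.08 ± 0.92, all with overlapping biopsies. THY1 had 1490, 2170 and 1554 counts in high replicates 1, 2 and 6, the libraries with the most COL1A2, and LUM had 50, 50 and 100 there against 12 to 36 in the other high biopsies. RELN and FAP, of the same list, did not follow, with their highest counts among the high biopsies in high replicates 4 (964) and 5 (264). At low counts, neither did COL6A3 (8, 14 and 12 in high replicates 1, 2 and 6, 20 in 4) nor COL1A1 (18, 16 and 2). DCN (24 in high replicate 2, 28 in 5) and LRAT (0 in high replicate 2) did not follow throughout. High replicates 1 and 2 came from the same construct.

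In the high construct, heat shock genes had a median distal over proximal ratio of -0.50, with 17 of 17 below 0, immediate early genes of -0.29, with 16 of 20, and NF-kB genes of -0.99, with 25 of 25 below 0. In the low construct the medians were 0.06, -0.14 and -0.19, with 5 of 17, 16 of 20 and 21 of 25 below 0. Among the ratios without replicates, the low construct lay below all random lists relative to HUVEC for cholesterol synthesis (-0.75), heat shock (-0.59), p53 targets (-0.57), tip cell genes (-0.56) and the unfolded protein response (-0.47). ATF4 targets (0.31) and ribosomal protein genes (0.12) lay above them all. HLSEC lay below all random lists relative to HUVEC for G2/M (-1.07), arterial (-1.03), cholesterol synthesis (-0.96), S phase (-0.77), ATF4 (-0.62), NF-kB (-0.62) and heat shock genes (-0.56), and above them for mesenchymal transition genes (0.59). Since the random lists drew genes independently, none of these positions is a test of a list whose members vary together.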
